A study of Homo sapiens with 2 samples.

How the data were processed

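Poly(A) RNA was sequenced from MDA-MB-231 cells, an established human triple-negative breast cancer line, after transfection with a negative control siRNA (1 library) or an siRNA against USP30-AS1 (1 library). Per the labels' protocols, RNA was extracted with Trizol, enriched with oligo(dT) beads, fragmented and made into libraries with a NEBNext Ultra RNA kit. The submitters' processing notes name fastp 0.18.0, HISAT2, StringTie 1.3.1 and RSEM, and the genome build GRCh38. The role of each tool, the annotation release and the strand setting of the counting were not given in the sources used here.

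The values came from 1 deposited table of 20289 genes. Per the file headers it holds read counts and FPKM for each library. The deposited counts are estimated counts per gene that the authors made before any normalization, taken here as estimated because RSEM is named and because 12.0% of the control values and 11.4% of the knockdown values were not whole numbers. The deposited FPKM values are normalized by the authors for transcript length and mapped fragments, per the file headers. A further pair of columns repeats the FPKM with 0 replaced by 0.001. The log2 fold change in the authors' deposited table is the ratio of those columns, and this was checked for every gene. The authors' deposited p-values and FDR come from a test that is not stated, and with 1 library per group no replicate entered it. They were counted and not used for any comparison. The table names its columns Si-NC and Si-179. The table itself is titled for the control against the USP30-AS1 siRNA and Si-NC matches the control label, so the remaining column was taken as the knockdown library. What 179 stands for is not given in the sources used here. No per-sample column was left unused.

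Expected counts were rounded to whole numbers. Library totals were 23287817 counts (control) and 19569214 (knockdown). Counts were divided by the library total (CPM) and scaled by TMM factors of 1.017 and 0.983 from edgeR 4.0.16 in R 4.3.3. The log2 ratio of a gene was log2((knockdown CPM + 0.5)/(control CPM + 0.5)), so a negative value means a lower level in the knockdown library. The added 0.5 pulls the ratios of low genes toward 0. Folds were computed without it, from the scaled CPM. A gene was compared if the mean of both libraries was at least 50 counts. It was counted as higher or lower if its log2 ratio was at least 1 in size, a difference of at least 2-fold. With 1 library per group there was no test and no p-value between the groups. Folds carry 95% exact (Clopper-Pearson) counting intervals, and shares of counts or of genes carry 95% Wilson intervals. These cover counting error only, and PCR copies of a molecule are not independent, so they say nothing of the spread between cultures.

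Genes were named by a rule fixed before the data were examined. It takes the genes around USP30-AS1, the 12 highest and the 12 lowest log2 ratios among genes with a symbol and a mean of at least 100 counts, up to 4 members of each gene list with the largest ratios, and the 5 most abundant genes. Copies of these genes, regulators and members of the interferon list, and markers used in the closing tests are named in addition, and were chosen after values were seen. Not all genes that the rule takes are reported here. The 36 gene lists (803 distinct genes) were also fixed beforehand. They cover genes around USP30-AS1, mitochondrial function, metabolism, cell cycle, cell death, innate immunity, differentiation, stress, signalling, and markers of leukocytes, fibroblasts, endothelial cells and red cells. For each list the median log2 ratio of members past 50 counts was set against the medians of 10000 random lists of the same size, matched by decile of mean expression. The percentile is a description of these libraries and not a p-value. List medians carry exact binomial 95% intervals over members, which are not independent.

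Gene coordinates, gene types, transcript GC content, transcript length and 3' UTRs were taken from GENCODE release 29 (GRCh38), to which 20171 of the 20289 gene identifiers matched and 118 did not. Another 583 entries had no symbol and kept their place in the totals. The 3' UTRs of 11344 compared genes were searched for every word of 7 bases present in at least 50 genes (16198 words). Each word was scored by how far the log2 ratios of its carriers lay from those of other genes, in standard errors across genes, after 3' UTR length, 3' UTR GC content and expression level were regressed out. The scores were set against 1000 shuffles of the ratios. The pathways of the deposited annotation were summarised like the lists, with 2000 random lists each. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

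The steps were tested on simulated data for this comparison, with counting noise only and 200 changed genes (11524 genes past the floor). A 4-fold increase passed the 2-fold rule in 100.0% of 50 genes and a 4-fold decrease in 96.0% of 50. No gene changed 1.5-fold either way passed, and 0.0% of unchanged genes did. A word whose carriers were lowered by 0.2 in shuffled ratios came back at rank 1 of 16198. The alternatives tried were size factors from DESeq2 1.42.0, FPKM in place of counts, pseudocounts of 0.1 and 1, no floor or a floor of 200 counts, 1.5-fold and 4-fold rules, a counting interval that excludes no difference, protein-coding genes alone, and list members found in 1 list only. FPKM were also given a pseudocount of 0.5, which weighs more on low FPKM than on CPM, so FPKM with a pseudocount of 0.01 was tried too. That setting, removal of GC and length trends, and genes free of certain 3' UTR words were added after the data were seen.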

Results

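The series measured poly(A) RNA in MDA-MB-231 cells, a mesenchymal-like human breast cancer line that lacks hormone receptors, and asked how gene expression differs when the long non-coding RNA USP30-AS1 is targeted by siRNA. One library came from cells given a negative control siRNA (23287817 counts) and 1 from cells given the USP30-AS1 siRNA (19569214 counts), which is called the knockdown library here. Counts were above 0 for 15050 genes in the control and 14738 in the knockdown library. A count of 0 allows up to 0.127 CPM in the control and 0.156 CPM in the knockdown library (3 counts). No difference between these libraries has a replicate check, so the values below describe 1 culture of each kind.

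USP30-AS1 itself was not analysed here, so the values do not show how far it was silenced. It is annotated on the minus strand of chromosome 12, from 109052350 to 109053952 (GRCh38), inside USP30, which is transcribed in the opposite direction from 109023089 to 109088026. Of its 656 exonic bases, 233 lie in exons of USP30. USP30, a deubiquitinase of the outer mitochondrial membrane that opposes mitophagy, had 487 counts in the control and 246 in the knockdown library, 1.61-fold lower (95% counting interval 1.38 to 1.88; log2 ratio -0.66). In FPKM its log2 ratio was -0.30, outside that interval. The strand setting of the counting is not known, so reads of USP30 and its antisense partner cannot be told apart. Among the surrounding genes, UBE3B, a ubiquitin ligase, was 1.59-fold lower (1.49 to 1.70) and MMAB, an enzyme of cobalamin metabolism, was 1.88-fold lower (1.65 to 2.14). The log2 ratios of ALKBH2, UNG, ACACB, KCTD10, MVK and SSH1 lay between -0.20 (MVK) and 0.27 (KCTD10). FOXN4, SVOP and DAO had 0 counts in both libraries and MYO1H had 10 and 3. None of the 9 compared genes around USP30-AS1 reached 2-fold. Their median was -0.16, at percentile 10.2 of random lists, within the range that such lists gave. CMKLR1, from 108288044 to 108339341 on the same chromosome, lies beyond SSH1 and was not on this list. It was 19.9-fold lower (11.7 to 36.8). Genes between CMKLR1 and SSH1 were not examined as a set.

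**Figure D1:**
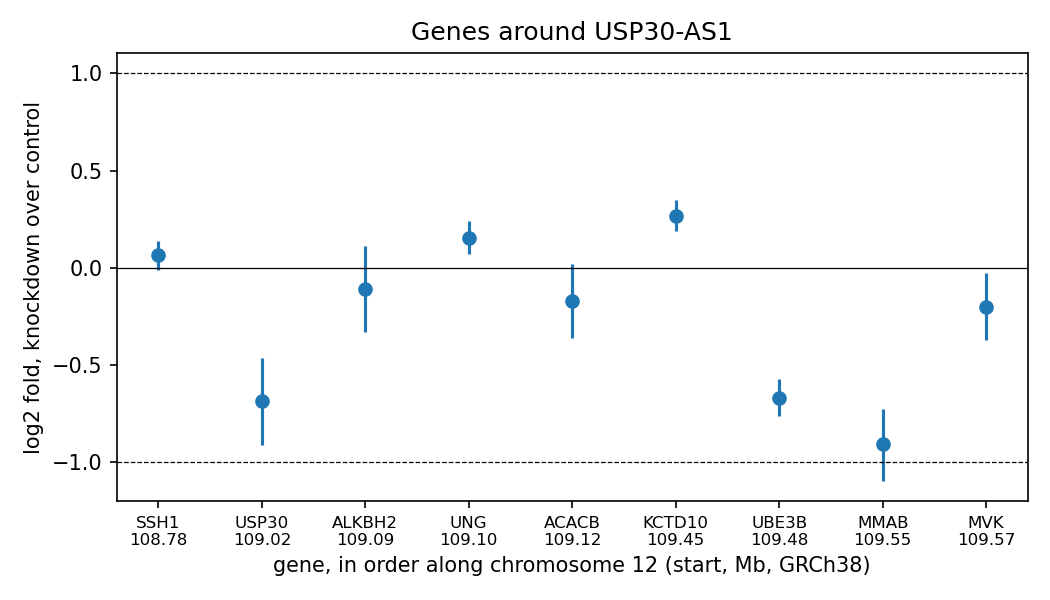
Log2 fold (knockdown over control, y axis) of the 9 compared genes around USP30-AS1, in order of their start on chromosome 12 (x axis, Mb, GRCh38), 1 library per group. Points are folds of scaled CPM, bars are 95% counting intervals, and dashed lines mark 2-fold. USP30, UBE3B and MMAB lie lowest and no point passes 2-fold.

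Most genes had similar levels in both libraries. Of 11530 genes compared, 10015 (86.9%) lay within 1.5-fold, and 364 (3.16%) differed by at least 2-fold, 185 of them lower and the others higher in the knockdown library. The lowest group held CMKLR1, the receptor of chemerin, at 343 counts in the control and 14 in the knockdown library (19.9-fold lower, 11.7 to 36.8). It also held several products of the interferon response: IFI44L was 11.3-fold lower (8.52 to 15.2), BST2, which tethers budding virions, 12.1-fold lower (7.87 to 19.6), IFITM1 5.48-fold lower (3.85 to 8.01) and MX1 4.45-fold lower (3.96 to 5.01). MUC5AC, a secreted gel-forming mucin and an abundant transcript of the control library, had 17802 counts there and 1907 in the knockdown library (7.58-fold lower, 7.23 to 7.95). LEFTY1, an antagonist of Nodal signalling, was 9.79-fold lower (6.20 to 16.3), and JUP, the junction protein plakoglobin, 4.02-fold lower (3.79 to 4.26). AHRR, the repressor of the aryl hydrocarbon receptor, and CYP1B1, a cytochrome P450, were 9.92-fold (6.21 to 16.8) and 3.97-fold (3.69 to 4.27) lower. SLC6A19, an amino acid transporter, was 4.46-fold lower (3.44 to 5.85). SERF1A had 233 and 14 counts, but it has a near-identical copy, SERF1B, which had 164 and 271, so its ratio is uncertain.

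At the other end, LYPD3, a surface protein of epithelial cells, had 24 counts in the control and 200 in the knockdown library (10.3-fold higher, 6.70 to 16.4). HPRT1, which salvages purines, was 4.37-fold higher (3.99 to 4.79), and PRPS2, which makes the ribose donor for purine synthesis, 4.62-fold higher (4.08 to 5.23). The transcription factor FOXQ1 was 4.60-fold higher (3.89 to 5.47), the methyl-DNA binding protein MBD2 4.04-fold higher (3.63 to 4.50), and the water and glycerol channel AQP3 4.14-fold higher (3.39 to 5.07). MPP4, MARCHF4, TMEM158, LAT2 and ESAM were 3.84-fold (ESAM) to 5.87-fold (MPP4) higher. RGPD6 had 19 and 643 counts (log2 ratio 4.70, and 3.02 in FPKM with a pseudocount of 0.01, below the 3.28 of LYPD3), but it belongs to a family of near-identical copies and RGPD5 had 1791 and 729 counts, so its ratio is uncertain. In the authors' deposited table, 887 genes had an FDR under 0.05 and a log2 fold of at least 1 in size, 348 of them higher and 539 lower. Of these, 427 lay under the floor of 50 mean counts used here and 89 had an FPKM of 0 in 1 library. The authors' deposited table and the 2-fold rule shared 332 of the 364 genes.

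**Figure D2:**
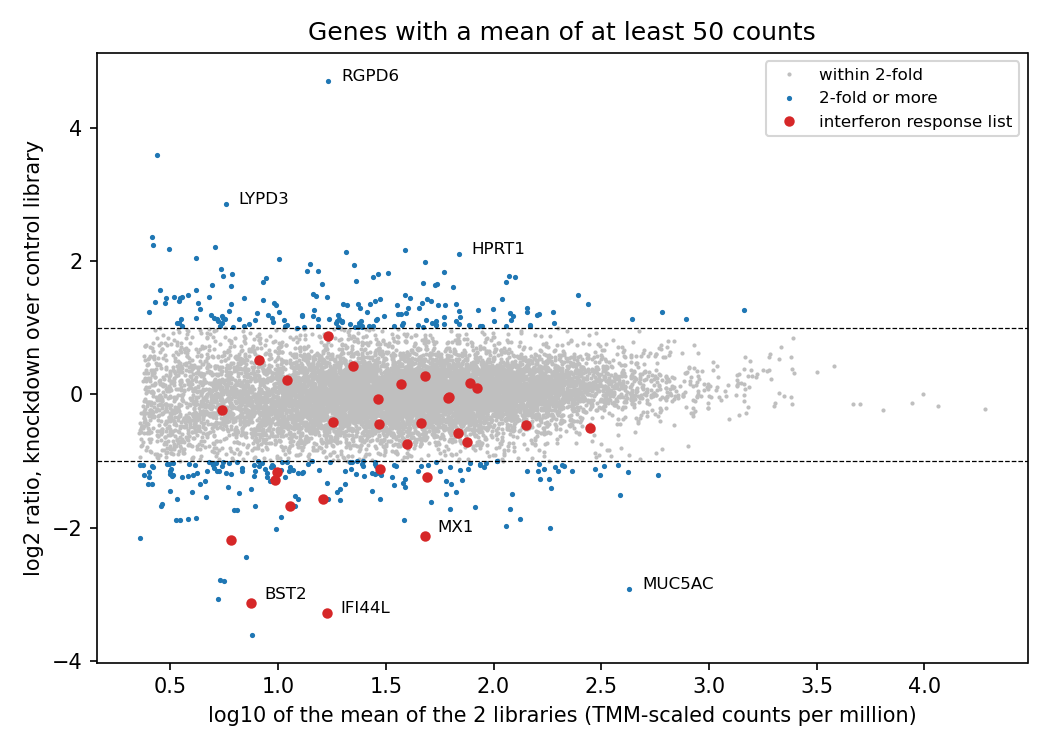
Log2 ratio (knockdown over control library, y axis) against log10 of the mean TMM-scaled CPM of both libraries (x axis) for the 11530 compared genes, 1 point per gene. Dashed lines mark 2-fold, the 364 genes past it are blue and the 30 compared genes of the interferon response list are red. Of the red points, 10 lie below the lower line and none above the upper line.

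The 3' UTRs of the genes past 2-fold differed in sequence. Of the 180 lower genes with an annotated 3' UTR, 70 (38.9%, Wilson interval 32.1 to 46.2) carried the word AACTCCA or ACTCCAA, called the low word below, where 17.9% would at matched 3' UTR length. Of the 174 higher genes, 81 (46.6%, 39.3 to 54.0) carried CCTAAGA or CTAAGAA, the high word, where 18.7% would at matched length. These words were picked on the same data. CMKLR1, SERF1A, its copy SERF1B and JUP carry the low word, PRPS2, HPRT1 and MBD2 the high word, and CYP1B1 both, while IFI44L, BST2, IFITM1, MX1, MUC5AC, LYPD3 and FOXQ1 carry neither. Of the other named genes not marked as carriers where their values stand, KCTD10, MMAB, TRIM25, CXCL8, IRF7, AGO4, LAT2, TP53INP1, BAD, TAPBP, SERPINH1 and H2BC21 carry the low word. LEFTY1, AHRR, BNIP3L, BAK1, CDKN1A, SUSD6, INSIG1, PGF, DUSP1, DICER1 and PECAM1 carry the high word, and SSH1, MCL1, DUSP4, NRP2, AGO1 and AGO2 carry both. Without carriers of either word, 86 higher and 103 lower genes were left.

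Interferon response genes were lower as a group. Of 30 compared members, 10 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -0.45 (-1.12 to -0.06), below all 10000 random lists (percentile 0.0). Besides IFI44L, BST2, IFITM1 and MX1, the 10 included IRF7 and IRF9, transcription factors of the response, with log2 ratios of -1.67 and -1.23. These and the other interferon genes in this paragraph were named after their values were seen. STAT2, which acts with IRF9, had a log2 ratio of -0.72. Another 8 members lay above 0, among them ISG15 (0.17), IFIT2 (0.27) and OASL (0.88). The median was -0.47 in the 22 members with neither word, again at percentile 0.0. The sensors and adaptors of RNA that feed this response had a median of -0.08 (percentile 17.3), which was 0.07 with a floor of 200 counts and 0.24 without carriers of either word (percentile 94.7), with TRIM25 at -0.46 and RIG-I (DDX58) at 0.42. Antigen presentation genes lay at 0.03 (-0.05 in FPKM; percentile 58.7), with CD274, which encodes PD-L1 and carries the high word, 2.97-fold higher (2.29 to 3.88) and TAPBP at -0.62. NF-kB and cytokine genes lay at 0.16 (percentile 94.0), or at 0.07 with a floor of 200 counts, with CXCL8 at 0.81 and IL11 at -0.72.

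Listed genes of glycolysis and of the hypoxia response were higher as groups. In glycolysis, 17 of 22 members lay above 0 and the median was 0.44 (0.29 to 0.71; percentile 100). ENO2 was 2.07-fold higher (1.93 to 2.23) and passed the 2-fold rule, while HK2 was 1.76-fold (1.63 to 1.90) and PGK1 1.66-fold higher (1.63 to 1.70). The hypoxia list had a median of 0.25 (-0.01 to 0.51; percentile 99.7), or 0.40 without carriers of either word, with 3 of 20 members at least 2-fold higher and 1 lower. NDRG1 was 3.39-fold (3.19 to 3.61) and ANGPTL4 2.74-fold higher (2.43 to 3.11), ANKRD37 had a log2 ratio of 1.18, and ADM was 2.32-fold lower (2.04 to 2.64). In the deposited annotation, the glycolysis pathway (43 genes) lay at 0.183 (percentile 99.9). The HIF-1 signalling pathway (83 genes) lay at 0.057 (percentile 78.35), within the random range. All 13 mitochondrially encoded mRNAs lay below 0, with a median of -0.15 (-0.22 to -0.12; percentile 0.44), or -0.25 after GC and length trends were removed, and their share of all counts was 6.97% (6.96 to 6.99) in the control and 5.96% (5.94 to 5.97) in the knockdown library. Nuclear genes of oxidative phosphorylation had a median of -0.06 (percentile 5.43), or -0.10 in FPKM, with CYCS, which carries the low word, at -0.73. The oxidative phosphorylation pathway of the deposited annotation (122 genes) lay at -0.049 (percentile 2.1), just below the random range. Genes of mitophagy and mitochondrial dynamics, the process USP30 acts in, had a median of -0.01 (-0.09 to 0.20; percentile 26.8), which was 0.00 with DESeq2 size factors, and none of the 26 reached 2-fold. The mitophagy receptors BNIP3 and BNIP3L were 1.63-fold (1.52 to 1.74) and 1.58-fold higher (1.51 to 1.65). Autophagy and lysosome genes lay at 0.14 (percentile 95.5), or at -0.01 without carriers of either word (percentile 36.2), with ATG5, which carries the high word, 2.75-fold higher (2.48 to 3.05), and ATG13, which carries the low word, 1.99-fold lower.

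Listed genes of proliferation and listed regulators of apoptosis were higher by small amounts. The G1/S and DNA replication list had a median of 0.27 (0.06 to 0.43; percentile 99.98), with 21 of 29 members above 0. GINS1, a part of the replicative helicase that carries the high word, had a log2 ratio of 1.76 (291 and 824 counts), and PCNA was 1.62-fold higher (1.54 to 1.70). In the G2/M list 24 of 31 members lay above 0 (median 0.23, 0.14 to 0.32; percentile 99.9) and none reached 2-fold. DNA repair genes had a median of 0.22 (percentile 99.9), with CHEK1 at 0.53 and CHEK2 at -0.59, and the median was 0.06 in FPKM. Apoptosis regulators had a median of 0.36 (-0.04 to 0.63; percentile 100) with none at 2-fold. This list mixes death-promoting and survival genes, and BAK1, which promotes death, and MCL1 and BIRC3, which oppose it, were 1.85-fold to 1.88-fold higher, while BAD, which promotes death, had a log2 ratio of -0.71. In the deposited annotation, the apoptosis (109 genes) and necroptosis (102 genes) pathways lay at 0.059 and 0.063 (percentiles 89.28 and 89.05), within the random range. A smaller apoptosis pathway (26 genes) lay at 0.31 (percentile 100). Targets of p53 lay at 0.03 (-0.01 in FPKM; percentile 71.2) and went both ways, with TP53INP1 1.96-fold lower (1.67 to 2.30), SUSD6 at -0.62, CDKN1A at 0.83 and FAS at 1.07, which was 0.83 in FPKM with a pseudocount of 0.01. The p53 signalling pathway of the deposited annotation (62 genes) lay at 0.127 (percentile 99.3), above the random range. MYC targets and ribosome biogenesis genes lay at 0.19 (percentile 98.3), although RRP12, which carries the low word, was 3.32-fold lower (3.03 to 3.65). The percentile of that list was 95.6 without carriers of either word. Cytosolic ribosomal protein genes lay at -0.02 (percentile 1.13), within 1.5-fold for most members, with RPS15 2.11-fold lower (2.02 to 2.21) and RPS2 at 0.56. Their median was -0.07 in FPKM and -0.06 after GC and length trends were removed. The larger ribosome pathway of the deposited annotation (131 genes) lay at 0.004 (percentile 5.78), within the random range. In these poly(A) libraries only 7 of 23 listed replication-dependent histone genes passed the floor. They had a median of 0.32 (percentile 97.0), or 0.71 with a floor of 200 counts and 0.25 without carriers of either word (percentile 86.1), with H1-2 at 1.10 and H2BC21 at -0.76.

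Genes of cholesterol synthesis were lower as a group. In cholesterol synthesis 19 of 23 members lay below 0, with a median of -0.24 (-0.40 to -0.06; percentile 0.04). INSIG1, a sterol-regulated brake of the pathway, was 2.05-fold (1.91 to 2.19), MVD 1.99-fold (1.74 to 2.27) and HMGCS1 1.61-fold lower (1.53 to 1.70). In the deposited annotation, steroid biosynthesis (16 genes) lay at -0.084 (percentile 11.6) and terpenoid backbone biosynthesis (20 genes) at -0.137 (percentile 3.0). Both were lower by less and within the random range. Fatty acid genes went both ways, with 13 of 24 below 0 and a median of -0.11 (-0.34 to 0.07; percentile 1.57), with FADS1 2.23-fold (2.14 to 2.33) and FASN 1.77-fold lower (1.72 to 1.81), both carriers of the low word, and CPT1A, which moves fatty acids into mitochondria, 2.61-fold higher (2.37 to 2.88). Without carriers of either word the fatty acid median was 0.05 (percentile 51.7). Of the 21 compared Wnt genes 8 lay above 0 and 1 was at least 2-fold lower, with a median of -0.31 (-0.50 to 0.16; percentile 0.09), or -0.17 with a floor of 200 counts. The larger Wnt pathway of the deposited annotation (108 genes) lay at 0.012 (percentile 54.3), with 56 genes above 0. CCND1, which encodes cyclin D1 and carries the low word, was 2.09-fold lower (2.02 to 2.16). Wnt feedback genes went both ways. AXIN2 and DKK1 were 2.10-fold (1.58 to 2.81) and 2.03-fold higher (1.76 to 2.34), while ZNRF3, which carries the low word, was 1.95-fold lower (1.64 to 2.34). Without carriers of either word the percentile of the Wnt list was 2.55. Oxidative stress and ferroptosis genes had a median of 0.23 (percentile 99.3), with ACSL4, a carrier of the high word, 2.29-fold higher (2.17 to 2.41), and the percentile was 94.5 without carriers.

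**Figure D3:**
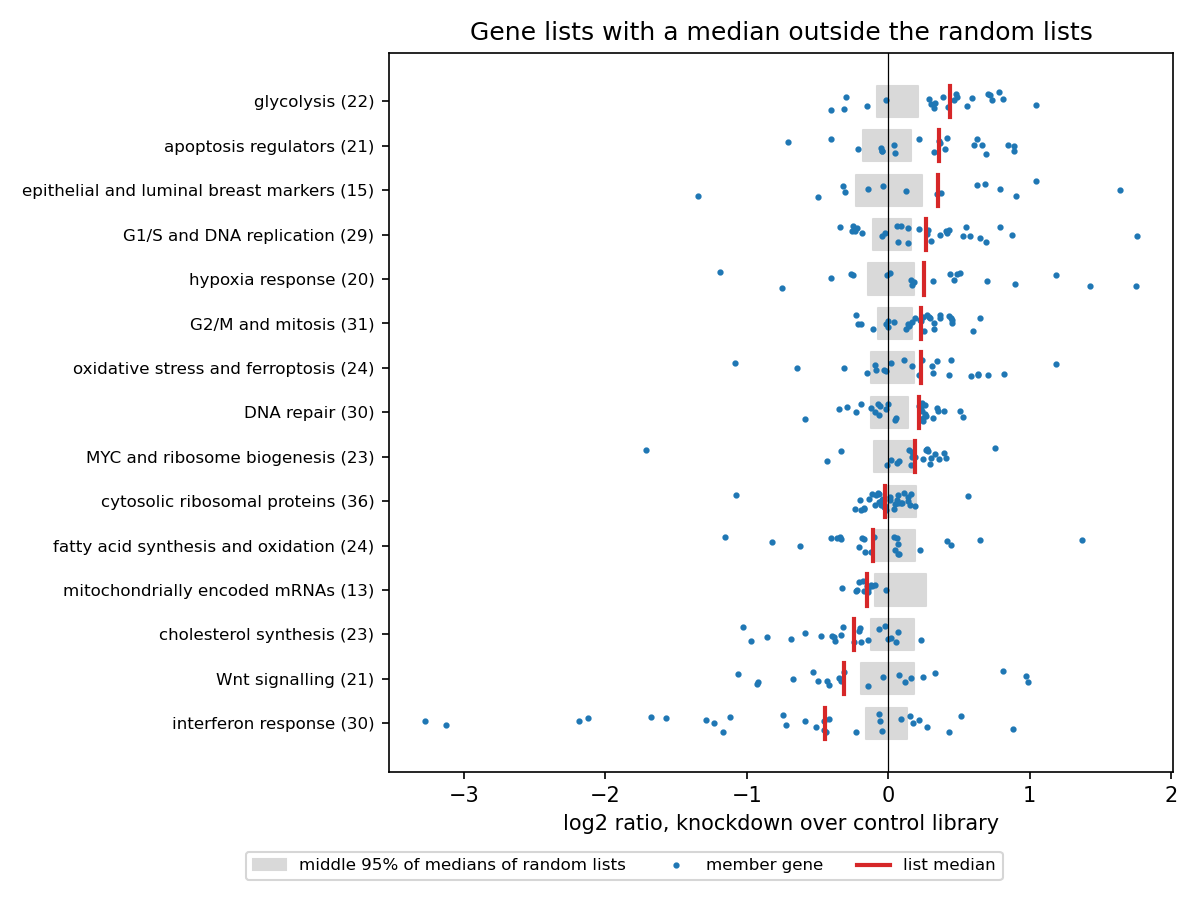
Log2 ratios (knockdown over control library, x axis) of the compared members of the 15 lists whose median lay outside the middle 95% of random lists, with the number of members in brackets. Blue points are genes, red bars list medians and grey bands the middle 95% of medians of 10000 random lists matched on expression. Glycolysis lies highest (median 0.44) and the interferon response lowest (-0.45).

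Epithelial and luminal markers had a median of 0.35 (-0.31 to 0.79; percentile 99.8) over 15 compared genes, which was 0.13 with no floor and 0.63 with a floor of 200 counts. Keratin 19 (KRT19) was 3.16-fold (2.88 to 3.48) and the tight junction gene CLDN4 2.08-fold higher (1.89 to 2.29), whereas the protease ST14 was 3.15-fold lower (1.99 to 5.16). Genes of the epithelial-mesenchymal transition lay at 0.11 (percentile 80.7), or at 0.02 with a floor of 200 counts and 0.00 without carriers of either word, with the surface receptor CD44, a carrier of the high word, 2.55-fold higher (2.45 to 2.65). TGF-beta targets lay at 0.01 (percentile 47.8), with the receptor TGFBR2, a carrier of the low word, 2.19-fold lower (2.08 to 2.30) and the ligand BMP4 at 1.01, which was 0.98 in FPKM with a pseudocount of 0.01. YAP/TAZ targets lay at 0.06 (percentile 60.3), or at -0.17 without carriers of either word (percentile 0.60), and among them CCN1 was 2.31-fold lower (2.25 to 2.37) and IGFBP3, a carrier of the high word, 3.80-fold higher (3.16 to 4.59). Immediate early and MAPK feedback genes lay at 0.06 (percentile 63.9), or at 0.20 without carriers of either word, with DUSP4 at -0.77 and DUSP1 at -0.70. Genes of angiogenesis and growth factor ligands lay at 0.13 (percentile 92.4). Their median was -0.01 with a floor of 200 counts and without carriers of either word. Of these 18 genes 2, IGFBP3 and ANGPTL4 (log2 ratio 1.43), were at least 2-fold higher and 0 at least 2-fold lower. NRP2 lay at 0.85 and PGF was 1.90-fold lower (1.72 to 2.11). The unfolded protein and integrated stress response lay at 0.08 (percentile 81.1, and 0.02 in FPKM), heat shock genes at 0.23 (percentile 96.5) with HSP90AA1 1.79-fold higher (1.77 to 1.81) and SERPINH1 at -0.58, and the small RNA machinery at -0.12 (percentile 9.96, and -0.03 in FPKM) with AGO1 at -0.48, AGO4 at -0.39, AGO2 at 0.28 and DICER1 at 0.45.

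Markers of other cell types were few. Of 20 leukocyte markers 3 passed the floor (median 0.36, percentile 92.3, and 0.03 with no floor), and CD68 (log2 ratio 0.43) and LAPTM5 (0.36) made up most of their counts. The remaining one, CD8A, had 77 and 31 counts, 2.02-fold lower (1.31 to 3.17). The 4 compared fibroblast markers had a median of -0.13 (percentile 34.8), which was 0.14 with no floor and -0.71 with a floor of 200 counts, and went both ways, from -0.93 (FBLN1) to 0.59 (COL1A1). The 4 endothelial markers had a median of 0.02 (percentile 59.1), which was -0.02 in FPKM and 0.34 with a floor of 200 counts, from -0.49 (PECAM1) to 1.85 (ESAM), and no haemoglobin gene passed the floor. The 5 most abundant genes were MT-CO1, MT-ND4, EEF1A1, MT-CO3 and MT-ND2, whose log2 ratios lay between -0.23 (MT-ND2) and 0.00 (EEF1A1). In all, 15 of the 35 lists with a value lay outside the middle 95% of random lists, 6 below and 9 above, where 1.8 would by chance if lists were independent. Lists share genes and their members move together, so that number is only a guide.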

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

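FPKM with a pseudocount of 0.01, removal of GC and length trends and the use of genes with neither 3' UTR word were chosen after the data were seen. The count of genes at least 2-fold apart (364) was 302 in FPKM with the pseudocount of 0.5 and 464 with 0.01, 362 with DESeq2 size factors, 422 and 310 with pseudocounts of 0.1 and 1, 539 without a floor, and 348 after GC and length trends were removed. It was 360 in protein-coding genes, and 364 with a counting interval that excludes no difference, which genes past the floor and 2-fold could hardly fail. By construction it moved further with a floor of 200 counts (233), the 1.5-fold rule (1515) and the 4-fold rule (24). In genes with neither word it was 189, or 2.45% of 7715 genes against 3.16% of all. The words were picked on the same data for the extreme ratios of their carriers. A lower share without carriers therefore follows largely from that choice and does not show what the words do. The interferon median (-0.45) lay between -0.51 and -0.44 under the alternatives run. Among lists outside the random range only the fatty acid median turned, to 0.05 in genes with neither word. After GC and length trends were removed 13 lists lay outside that range, and the fatty acid (percentile 6.85) and oxidative stress (95.9) lists no longer did. In FPKM the medians of p53 targets (-0.01), antigen presentation (-0.05) and endothelial markers (-0.02) took the other sign. In genes with neither word so did autophagy (-0.01), mitophagy (0.01), RNA sensing (0.24), antigen presentation (-0.01), TGF-beta targets (-0.03), YAP/TAZ targets (-0.17) and the angiogenesis list (-0.01). A floor of 200 counts turned RNA sensing (0.07), p53 targets (-0.01), TGF-beta targets (-0.03) and the angiogenesis list (-0.01), and no floor turned RNA sensing (0.01), mitophagy (0.01) and fibroblast markers (0.14). Members in 1 list only turned TGF-beta (-0.02) and YAP/TAZ targets (-0.06) and the angiogenesis list (-0.01), and removal of GC and length trends turned RNA sensing (0.05). The fibroblast median moved to -0.71 with a floor of 200 counts, where the histone median was 0.71. Of 51 named genes past 2-fold, 3 fell under it in FPKM with a pseudocount of 0.5 (FAS, BMP4 and ST14), 2 with 0.01 (FAS and BMP4) and 1 in counts with a pseudocount of 1 (FAS), and 91 of 825 values of named genes left their counting interval. No scaling moved the median of all genes further than to -0.036 (FPKM with a pseudocount of 0.01). The level of USP30-AS1 has no value here. DESeq2 as a test, leaving out replicates and the replicate block were not run, since each needs more than 1 library per group. No paired analysis was possible because each group has 1 library. Depth limits genes near the floor, where 50 mean counts leave wide counting intervals.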

Other observations

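Tests of the interferon genes and their regulators by 3' UTR word, of the 8-base words, of the leukocyte markers and of the aryl hydrocarbon receptor targets were chosen after some of the values they use had been seen, and the pathways here were looked at after the lists. Among 280 pathways of the deposited annotation, 22 had medians below and 35 above the middle 95% of matched random lists, where 14 would by chance if pathways were independent. Proteasome genes were higher by small amounts in the knockdown library, with 37 of 43 above 0, a median log2 ratio of 0.313 (0.267 in FPKM) and none at 2-fold. Spliceosome genes had a median of 0.164 (0.118 in FPKM), with 107 of 131 above 0 and none at 2-fold. Ribosome biogenesis lay at 0.194 with 55 of 71 above 0, and RNA transport at 0.151 with 99 of 146 above 0. At the other end, GPI-anchor biosynthesis had a median of -0.258, with 5 of 24 genes above 0, and Jak-STAT signalling -0.171, with 31 of 80 above 0.

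The first pattern is in the 3' UTRs, where of 16198 words ACTCCAA had the lowest score (-11.82) and CTAAGAA the highest (17.62), while 1000 shuffles reached -5.49 and 5.71. As a hypothesis, small RNAs that pair with these words may have silenced their carriers, the low word in the knockdown library and the high word in the control library. Genes with the 8-base AACTCCAA had a median of -0.198 (367 genes, -0.242 to -0.154), against -0.099 with a 7-base form only and 0.027 with none, and CCTAAGAA gave 0.171 (456 genes, 0.130 to 0.219), 0.068 and -0.021, a grading that such silencing predicts, although the 8-base words were built from words picked on the same data. The word AACTCCA at bases 177 to 183 of the USP30-AS1 transcript ranked second (-11.43), and ACTCCAT, which overlaps it from base 178, ranked 3 (-6.34), both beyond the shuffles, whereas the test asked for rank 1, 3.8% of all words lie in that transcript, and the siRNA sequences were not used here. Both words share ACTCCA with the lowest word, so they are not separate hits. The 3.8% holds for single words and understates how often some word of such an overlapping family would lie in the transcript. Read as a base of the transcript, the number in the name of the knockdown column falls inside AACTCCA. What it stands for is not given in the sources used here, and it may mark the start, the end or no point of a site. It therefore does not place a seed, and a seed of the USP30-AS1 siRNA and another source cannot be told apart. After GC and length trends were removed, 98.9% as many genes were at least 2-fold lower. With genes grouped by transcript GC content, group medians of the log2 ratio lay between -0.05 and 0.06. A GC trend of that size is far smaller than a 2-fold difference, and its removal could hardly change the count. The count also does not follow single genes or the words, so it does not decide whether GC or length bias contributed to this pattern.

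The second pattern is the lower interferon response. Leukocytes in the control culture as the main source are argued against, because 7 abundant leukocyte transcripts (PTPRC, CD3D, CD3E, CD79A, TYROBP, FCER1G and LYZ) summed to 9 counts there (at most 17.1), under 1% of the 5158 counts by which the 10 lower interferon genes exceeded in the control, although CD8A was 2.02-fold lower, and a first test on the sum of 20 markers (log2 ratio 0.36) was replaced because it rested on LAPTM5 and CD68. Silencing of the interferon genes themselves through the low word is argued against as the main source, because the 25 members without it had a median of -0.45 (-1.17 to -0.06), a wide interval, and the members with neither word lay at percentile 0.0, a criterion added after the values were seen. Silencing of a regulator may contribute as a hypothesis, since 1 of 8 regulators, IRF7 (415 and 99 counts), carries the low word and was at least 2-fold lower, and the receptor subunit IFNAR2 (716 and 357 counts, log2 ratio -0.69) carries it too, but IRF7 is itself induced by interferon and IRF9, without the word, was also lower. Of all genes within 2-fold 19.1% carry the low word, so some carriers among 8 regulators would be found without any link to the response. IRF7 is also 1 of the 10 lower interferon genes and so is not separate evidence. An innate response to the control siRNA and an effect of lower USP30-AS1 cannot be told apart without an untransfected library, and the interferon genes IFNB1 and IFNL1 had at most 5 counts in the control.

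The third pattern is the large ratios of genes with near-identical copies, where reads may have moved between copies in the counting. The 7 RGPD genes summed to 2607 and 1978 counts, a log2 ratio of -0.10 (-0.18 to -0.01), while RGPD6 stood at 4.70 and RGPD5 at -0.99 (-0.77 in FPKM with a pseudocount of 0.01). SERF1A and SERF1B summed to 397 and 285 counts, a log2 ratio of -0.18 (-0.40 to 0.04), with SERF1B at 0.97 (1.61 in FPKM with a pseudocount of 0.01). The test asked for an opposite 2-fold difference of the partner, and the counting intervals of both partners span it (RGPD5 1.83-fold to 2.18-fold lower, SERF1B 1.67-fold to 2.49-fold higher), so movement between copies and real differences cannot be told apart.

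A further hypothesis was that AHRR and CYP1B1 were lower because the aryl hydrocarbon receptor may have been less active in the knockdown library. The 4 other targets past the floor had a median of 0.14, in the range set to count against this hypothesis. They went both ways, from -0.56 (SLC7A5) to 0.73 (CYP1A1), so these 4 genes did not decide, and CYP1B1 carries both words.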
